A study of Mus musculus with 9 samples.

How the data were processed

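Small RNA was sequenced from whole kidneys of mouse embryos at embryonic day 16.5. There were 9 libraries in 3 groups of 3, and each library was assigned to its group by its title and genotype: wild-type control, DROSHA-E1147K transgene, and DROSHA knockout. Per the labels' protocols, kidneys were frozen on dry ice, RNA was extracted with Trizol, and libraries were made with the BGI small RNA protocol. The submitters' processing notes name CASAVA 1.8, Bowtie2 and the mouse genome build mm10, without giving the role or the order of each. The rule by which a read that matches several annotations or several miRNA names was assigned is not given in the sources used here. Nothing in the labels says whether the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

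The deposited counts are whole numbers of reads per small RNA name, and in each of the 9 files they add up to the total written in the header. The deposited TPM column is, per the file headers and the values, the count per 1e6 of that total, with a largest gap of 0.005, and it was not used for any test. Each name carries a class (mature miRNA, miRNA hairpin, Rfam family, repeat, intergenic, exon, intron and others). The main tests used known mouse miRNAs only, with mature and hairpin counts of 1 name added. The total per library was 31743004 to 42609889 reads, of which 24350500 to 34896599 were counted to known miRNAs under 1336 to 1401 names. The most abundant name took 6.39% to 11.3% of a library's miRNA reads and the 5 most abundant together took 23.0% to 28.6%. Replicates of every group differed by more than read sampling alone gives, which would also hold for separate preparations from 1 animal. The reads carry no molecular identifiers, so intervals given for read counts cover counting error only.

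The counts were tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM (factors 0.882 to 1.13), names with too few reads were removed with filterByExpr, and 955 miRNAs were fitted over all 9 libraries with the group as a factor of 3 levels. The quasi-likelihood F test gave each contrast, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.49. Values in CPM use the TMM-scaled totals of miRNA reads, and log2 fold changes are those of the edgeR fit. Members of 21 lists of miRNAs (families, genomic clusters, and markers of tubule, stroma, muscle, endothelium, erythroid cells, leukocytes, neurons, and pancreas and liver) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Unless another test is named, a list or genomic cluster is said to be called by camera with the preset correlation. That setting treats the members of a list as nearly independent. Lists, tests and the rule for naming miRNAs were fixed before the data were examined. The rule took, per comparison, up to 10 miRNAs with the highest and 10 with the lowest fold change among those past the threshold, with a mean of at least 10 CPM and groups that do not overlap. If fewer than 5 passed, the 5 with the smallest p-values were added and are said not to pass. It also took the 5 most abundant miRNAs of the controls and, as examples of each list described, 2 to 4 of its tested members with the highest mean CPM. Genomic clusters, a test added after the data were seen, were single-locus miRNAs with gaps of up to 50 kb and at least 4 tested, 34 in all, and were also tested with camera. A miRNA named outside the rule is said to have been chosen after its values were seen.

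Shares of reads by class, the ratio of 5p to 3p arms and, where given, list means per library were compared with exact two-sided permutation tests. Their smallest possible p with 3 libraries against 3 is 0.1. The test of list means was not among those fixed in advance. The arm ratio was the median over 306 hairpins of log2 of 5p over 3p counts, with a pseudocount of 1. Because both DROSHA groups were compared with the same 3 controls, the correlation of their fold changes was set beside 100 simulated draws. Each draw simulated all 9 libraries from the control means without a group difference, each miRNA independently. Loci came from the RefSeq annotation of the mm10 assembly and were compared with GENCODE vM21. Of the 955 miRNAs tested, 930 had a locus, and 636 of the 637 precursor loci had the same coordinates in GENCODE.

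The edgeR and camera steps were first tested on simulated counts for the knockout against control comparison, with 955 miRNAs, 200 of them changed, in 10 draws. The test recovered 14.2% of 2-fold changes, 68.6% of 4-fold changes, 90% of 8-fold changes and 94.4% of 16-fold changes, with 5.4 false calls per draw. A shift of 0.8 on the log2 scale placed on the cluster list of chromosome 12 was called in 10 of 10 draws, with 0.1 other lists called per draw. Simulated miRNAs were drawn independently, while the estimated correlation within that list was 0.69 in the data. The draws therefore do not show how often camera falsely calls lists of correlated miRNAs.

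The alternatives fixed in advance were RLE factors, total counts without composition factors, factors from a list of precursors processed without DROSHA, DESeq2 1.42.0, no filter on low counts, a filter of at least 10 CPM in 3 libraries, only the 2 groups compared, the replicate number as a block, other small RNA names included, the 5 most abundant miRNAs left out, and each library left out in turn. Added after the data were seen were a robust quasi-likelihood fit, voom with sample weights, scaling to all counted reads, mature entries only, identical mature sequences summed, other definitions of the mature miRNA share, and the same alternatives for genomic clusters. The summing covered only miR-199a-3p with miR-199b-3p, and both arms of miR-486a with those of miR-486b. Other names that may share a sequence, including those of the Sfmbt2 list, were not summed. An alternative for files with normalized values only did not apply, because the files hold counts. Sequences of other organisms were not reported. The arm ratio was also computed from summed counts and within replicate numbers.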

Results

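Small RNA sequencing covered whole kidneys of mouse embryos at embryonic day 16.5, with 3 wild-type control libraries, 3 libraries from kidneys with a DROSHA-E1147K transgene and 3 libraries from DROSHA knockout kidneys. DROSHA is the nuclear RNase III enzyme that releases hairpin precursors from primary miRNA transcripts, and E1147K changes a residue in one of its RNase III domains. The series concerns how losing or mutating DROSHA affects the developing kidney and Wilms tumor, a childhood kidney cancer. Between 24350500 and 34896599 reads per library belonged to known miRNAs. Drosha mRNA, the targeted gene, is not measured by this assay, so the genotype labels were not checked by it. The labels do not name the mouse lines or the cells in which Drosha was changed. Fold changes therefore describe whole kidneys, not cells known to lack DROSHA. miRNA names are mostly given without the species prefix (mmu-) of the files.

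Control kidneys were dominated by miR-10a-5p, which is encoded in the Hoxb cluster at chromosome 11:96317165-96317274 (mm10), at 97862 ± 11151 CPM (SD, n = 3). It was followed by miR-26a-5p at 58581 ± 3306 CPM, the endothelial miR-126a-3p at 47853 ± 5860 CPM, the erythroid miR-451a at 39999 ± 16632 CPM and let-7i-5p at 39687 ± 1317 CPM. miR-10a-5p stood at 62422 ± 18996 CPM in the transgene libraries and 44395 ± 16812 CPM in the knockout libraries (SD, n = 3 each), in both groups below all 3 controls. For the transgene this held only with TMM scaling. As an unscaled share of miRNA reads, miR-10a-5p took 7.615% in transgene 1 and 7.578% in control 2. miR-451a was at 54397 ± 26423 CPM with the transgene and 83718 ± 22534 CPM in the knockout.

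Reads assigned to mature miRNAs made up 81.5% ± 0.527 of all counted reads in controls, 78.1% ± 1.14 in transgene libraries and 76.1% ± 1.28 in knockout libraries (SD, n = 3 each). Every library of either DROSHA group lay below every control, by 3.44 percentage points on average for the transgene and 5.41 for the knockout. Repeat-derived reads were at 3.90% ± 0.327, 5.77% ± 1.06 and 6.18% ± 1.19 in the 3 groups, and Rfam microRNA families at 6.0% ± 0.300, 6.56% ± 1.04 and 8.21% ± 1.76. The rise of the families came from erythroid mir-451, at 1.74% ± 0.523, 2.90% ± 1.42 and 4.71% ± 1.93, while the other families fell from 4.27% ± 0.295 to 3.67% ± 0.486 (exact p 0.2) and 3.51% ± 0.176 (exact p 0.1). The exact two-sided permutation p for the mature share was 0.1 in each comparison with controls, the smallest that 3 against 3 libraries allow, and 0.5 for the transgene and 0.25 for the knockout after Benjamini-Hochberg adjustment over 15 classes. The size of the difference depended on the classes counted. It was -1.14 points for the transgene and -3.48 for the knockout with intron, exon, repeat and intergenic reads left out, and -2.87 and -3.19 with Rfam microRNA families added, where the knockout libraries overlapped the controls (exact p 0.2). With the families added and miR-451 left out it was -3.47 and -4.54, without overlap (exact p 0.1 each). Between knockout and transgene the share differed by -1.97 points (exact p 0.2). This was -1.24 (exact p 0.3) without knockout 1, -2.60 (exact p 0.1) without transgene 2, -2.35 (exact p 0.1) with intron, exon, repeat and intergenic reads left out, and -0.321 (exact p 0.7) with Rfam families added, or -1.06 (exact p 0.5) with miR-451 also left out.

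**Figure D1:**
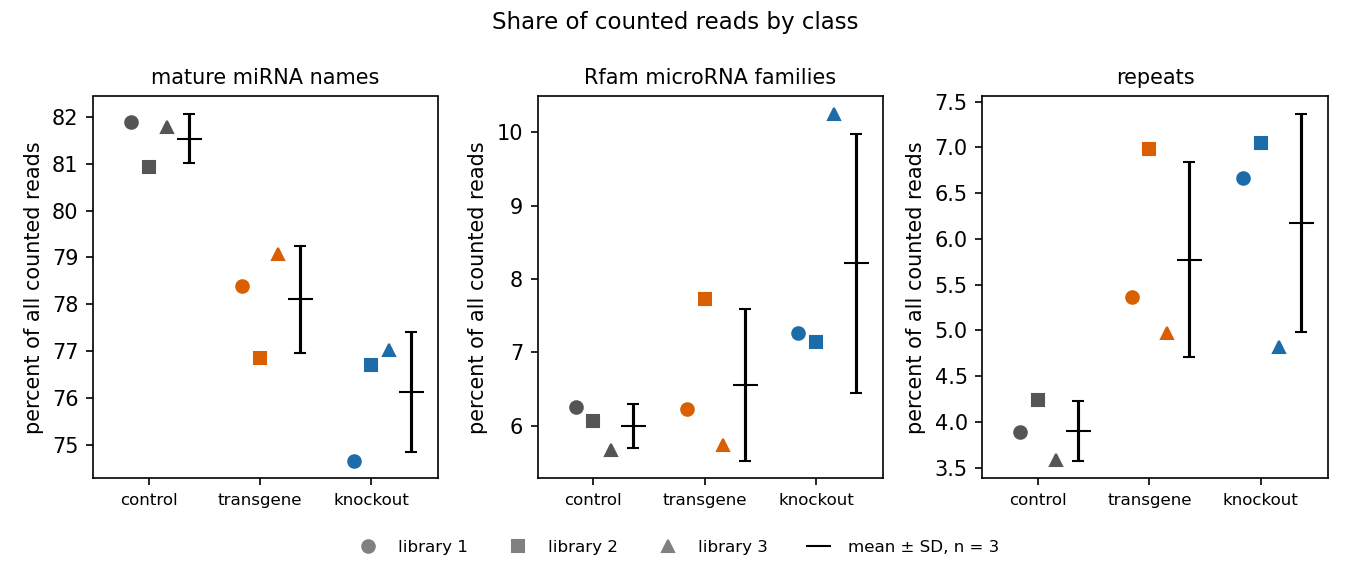
Share of all counted reads (percent) assigned to mature miRNA names, Rfam microRNA families and repeats, 1 point per library with the group mean and SD (n = 3). Mature names took 80.9% to 81.9% in controls, 76.9% to 79.1% with the transgene and 74.7% to 77.0% in the knockout.

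Against controls, the transgene libraries carried more of the miRNAs of the imprinted Dlk1-Dio3 region, a large maternally expressed cluster on chromosome 12 (109563692-109743795, mm10). The list was fixed by name and leaves out some miRNAs of the region, such as miR-673-3p. All 90 tested members of the list had positive log2 fold changes, with a median of 0.82, and the cluster rose as a list by camera (adjusted p = 5.6e-30, or adjusted p = 0.465 with an estimated correlation). Its lowest median over 24 alternatives was 0.42, with DROSHA-independent factors. miR-127-3p, encoded at chromosome 12:109592846-109592915, was at 10876 ± 1191 CPM against 6170 ± 795 in controls (log2 0.82, SE 0.29), and miR-411-5p was at 8194 ± 1273 against 5862 ± 280 CPM (log2 0.48, SE 0.31, and 0.32 without transgene 1). In 59 of the 90 members the 3 transgene libraries did not overlap the 3 controls. The list mean was 0.85 log2 units above the controls, with transgene libraries at 5.95, 6.58 and 5.84 and controls at 5.25, 5.17 and 5.38 log2 CPM. The exact permutation p of the list mean was 0.1, the smallest possible. Muscle and erythroid miRNAs had positive medians in the same libraries, 0.69 for the muscle list (adjusted p = 0.0781) and 0.44 for the erythroid list.

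Tubule miRNAs fell in the transgene kidneys. All 8 tested members of the tubule epithelium list were negative, with a median of -0.60 (camera adjusted p = 0.0049, or adjusted p = 0.230 with an estimated correlation). miR-192-5p was at 1474 ± 632 against 2079 ± 1009 CPM (log2 -0.50, SE 0.38), and miR-204-5p, from an intron of Trpm3, at 1329 ± 441 against 2150 ± 149 CPM (log2 -0.69, SE 0.31). The fold of mmu-miR-192-5p, transgene vs control, was -0.058 without control 3, -0.26 without transgene 3, -0.76 without control 2 and -0.84 without transgene 2, and that of mmu-miR-204-5p, transgene vs control, was -0.43 without transgene 2. The miR-17~92 clusters, whose miRNAs promote proliferation, fell with a median of -0.22 in 25 members, 24 of them negative (adjusted p = 0.0061, or adjusted p = 0.712 with an estimated correlation). Among them miR-92a-3p was at 19741 ± 614 against 27041 ± 5723 CPM and miR-93-5p, encoded within Mcm7, at 7251 ± 75.1 against 10514 ± 2114 CPM. The list means of the tubule and miR-17~92 lists did not overlap with controls (exact permutation p 0.1 each). The miR-30 family, abundant in kidney epithelium, fell with a median of -0.32 and all 11 members negative (adjusted p = 0.0149, or adjusted p = 0.465 with an estimated correlation). The miR-30 list means overlapped with controls (exact permutation p 0.2). The family's most abundant members miR-30d-5p and miR-30c-5p had log2 fold changes of -0.34 (SE 0.31) and -0.12 (SE 0.40), and the latter turned positive with scaling to total counts (0.13). The fold of miR-30d-5p was -0.14 without control 3, -0.22 without transgene 1 and -0.52 without transgene 3, and that of miR-30c-5p went from -0.33 without control 2 to 0.12 without control 3. Without transgene 1 the miR-17~92 call ended (adjusted p = 0.0656), its median was -0.36 without control 3 and -0.14 without knockout 1, and the miR-30 call ended without control 3 (adjusted p = 0.189). The miR-30 median was -0.16 without control 3, -0.50 without transgene 1 and -0.17 without transgene 2.

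The injury and inflammation list fell in the transgene kidneys with a median of -0.44, 9 of 10 members being negative (camera adjusted p = 0.0149, or adjusted p = 0.465 with an estimated correlation). Its members miR-21a-5p, at 17281 ± 3882 against 18393 ± 650 CPM, and miR-146a-5p, at 476 ± 53.1 against 552 ± 42.5 CPM, overlapped with controls, and the fold of miR-21a-5p (-0.09) turned positive with scaling to total counts (0.10) and went from -0.34 without transgene 1 to 0.089 without transgene 3. miR-146b-5p, which lies in an intron of Mfsd13a on chromosome 19:46342762-46342870 and targets inflammatory signalling, had the smallest p-value of the comparison, at 46.6 ± 4.12 against 98.2 ± 6.70 CPM (log2 -1.08, SE 0.20, edgeR adjusted p = 0.398).

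Erythroid miRNAs rose in the transgene libraries with a median of 0.44 in 7 members, all positive (camera adjusted p = 0.0499, or adjusted p = 0.712 with an estimated correlation), miR-451a at 0.44 (SE 0.44) and miR-144-3p at 1.10 (SE 0.57). The erythroid list means overlapped with controls (exact permutation p 0.2). The 7 names count miR-486a and miR-486b separately although their mature sequences are the same. With identical sequences summed the erythroid call ended, leaving 1 list called higher instead of 3. The fold of mmu-miR-451a, transgene vs control, was 0.020 without transgene 1, 0.11 without control 3 and 0.85 without transgene 3, and that of mmu-miR-144-3p, transgene vs control, was 0.72 without control 3. The call ended in 15 of 24 alternatives, among them without control 3 (median 0.27, adjusted p = 0.376), transgene 1 (0.20, 0.187), transgene 2 (0.37, 0.279), knockout 1 (0.52, 0.0804) and knockout 3 (0.52, 0.0690), and the median was 0.85 without transgene 3. The early-embryonic miR-290 and miR-302 clusters were called upward by the same margin (median 0.35, 9 of 15 positive, adjusted p = 0.0499, or adjusted p = 0.712 with an estimated correlation). The list means of these clusters overlapped with controls (exact permutation p 0.5). Their abundant members miR-292a-3p and miR-293-3p had log2 folds of 0.43 (SE 1.67) and 0.35 (SE 1.47), which went from -2.93 and -2.23 without transgene 1 to 3.88 and 2.92 without control 3. That call ended in 16 of 23 alternatives. It ended without control 1 (median -0.15, adjusted p = 0.178), control 2 (-0.18, 0.435), transgene 1 (-2.23, 0.719), knockout 1 (0.46, 0.0701), knockout 2 (0.36, 0.0613) and knockout 3 (0.44, 0.0911), and the median was 3.34 without control 3, 0.89 without transgene 2 and 0.93 without transgene 3.

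In edgeR's quasi-likelihood test no single miRNA passed in the transgene comparison, while 84 of 955 had an unadjusted p under 0.05 (50 higher, 34 lower, where chance gives 47.75) and DESeq2 called 2, miR-375-3p higher and miR-146b-5p lower. The 84 became 37 without transgene 2, 48 without control 1, 51 without control 2 and 155 without knockout 3. Groups did not overlap for 229 miRNAs, or 24.0%, where chance gives 10%. After miR-146b-5p the smallest p-values belonged to miR-322-5p (18365 ± 905 against 29656 ± 940 CPM, log2 -0.69, SE 0.14), miR-667-5p of the Dlk1-Dio3 region (3.0 ± 0.806 against 0.920 ± 0.131 CPM, log2 1.70, SE 0.37), the endocrine miR-375-3p (4781 ± 3779 against 444 ± 152 CPM, log2 3.43, SE 0.77) and miR-341-3p of the Dlk1-Dio3 region (1227 ± 305 against 568 ± 32.3 CPM, log2 1.11, SE 0.27). None of these passed, with edgeR adjusted p from 0.398 to 0.458. Of the most abundant miRNAs, miR-10a-5p had a log2 fold of -0.65 (SE 0.31), let-7i-5p of -0.45 (SE 0.16), miR-126a-3p of -0.26 (SE 0.18), miR-26a-5p of -0.26 (SE 0.17) and miR-451a of 0.44 (SE 0.44). Without transgene 2 the folds of miR-10a-5p, miR-126a-3p and miR-26a-5p were -0.41, -0.10 and -0.079, and that of miR-26a-5p was -0.48 without transgene 1 and -0.14 without transgene 3. Adjusted over the list alone, 2 miRNAs of the injury list were lower and 1 of the pancreas and liver list was higher.

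The other lists did not pass in the transgene comparison. Their medians were -0.20 for let-7 (camera adjusted p = 0.0781, turning positive with total counts), -0.37 for the Hox cluster miRNAs (0.0869) and -0.40 for miR-34 and miR-449 (0.0781). The epithelial miR-200 family at -0.12 (0.331), miR-99/100 and miR-125 at -0.10 (0.331), and the Sfmbt2 list (miR-297, miR-466, miR-467 and miR-669 names) at -0.04 with a test direction of up (0.521) turned positive with total counts or all counted reads. Stroma and smooth muscle at 0.00 (0.822), leukocytes at 0.30 (0.331), neural miRNAs at 0.04 (0.484), pancreas and liver at 0.07 (0.331), the Igf2 and H19 hosted miRNAs at 0.14 (0.633), precursors processed without DROSHA at 0.10 (0.331) and endothelium at 0.06 with a test direction of down (0.999) turned negative with DROSHA-independent factors. Those factors are computed from the list of precursors processed without DROSHA, so the mean of that list under them is fixed near 0 and tests nothing. Total counts moved the median of all miRNAs to 0.18, all counted reads to 0.12 and DROSHA-independent factors to -0.40. The share of higher miRNAs among those with an unadjusted p under 0.05 was 59.5% with TMM, 93.9% with total counts, 87.1% with all counted reads and 30.0% with the DROSHA-independent factors.

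In knockout kidneys the same cluster was higher. All 90 miRNAs of the Dlk1-Dio3 list had positive log2 fold changes against controls, with a median of 1.31, and the cluster rose as a list (camera adjusted p = 1.2e-28, or adjusted p = 0.338 with an estimated correlation). miR-127-3p was at 13545 ± 6038 against 6170 ± 795 CPM (log2 1.13, SE 0.29) and miR-411-5p at 10618 ± 4949 against 5862 ± 280 CPM (log2 0.86, SE 0.31, and 0.54 without knockout 3). Adjusted over the list alone, 68 of the 90 miRNAs were higher, and over all miRNAs tested 0 were. The library knockout 3 stood apart, with a list mean of 7.29 log2 CPM against 5.81 and 6.0 in knockouts 1 and 2 and 5.17 to 5.38 in controls. Without it the cluster median was 0.81 (camera adjusted p = 3.9e-18). With all libraries, the exact permutation p of the list mean was 0.1, the smallest possible.

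The same library was rich in muscle and erythroid miRNAs, and was the highest knockout library for neural (1.89 above the control mean), pancreas and liver (1.62) and leukocyte (1.19) markers. Transgene 2, the highest transgene library for Dlk1-Dio3 (1.31), was likewise the highest of its group for pancreas and liver (1.96), erythroid (1.30), neural (1.20, as in control 1) and leukocyte (0.94) markers. The muscle list rose with a median of 2.72, 9 of 10 members being positive (camera adjusted p = 0.0058, or adjusted p = 0.522 with an estimated correlation), but its list mean was 6.64 log2 CPM in knockout 3 against 4.35 and 2.56 in the other knockouts and 1.94 to 3.74 in controls. Myogenic miR-206-3p was counted at 6895 CPM in knockout 3 and at 1242 and 186 CPM in the others, against 852, 101 and 97.8 CPM in controls, with a log2 fold of 2.99 (SE 1.33), and miR-499-5p of Myh7b had a fold of 2.22 (SE 0.81). These folds were 1.09 and 0.89 without knockout 3, and that of miR-206-3p was 4.75 without control 1. Without knockout 3 the muscle call ended (median 0.99, adjusted p = 0.193). Erythroid miRNAs rose with a median of 1.16 and all 7 members positive, with miR-486a and miR-486b again counted separately (adjusted p = 0.0058, or adjusted p = 0.379 with an estimated correlation, and 0.0493 without knockout 3). Their examples miR-451a and miR-144-3p, neighbours on chromosome 11, had folds of 1.07 (SE 0.45) and 1.39 (SE 0.58), the second at 0.88 without knockout 3 (mmu-miR-144-3p, knockout vs control).

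**Figure D2:**
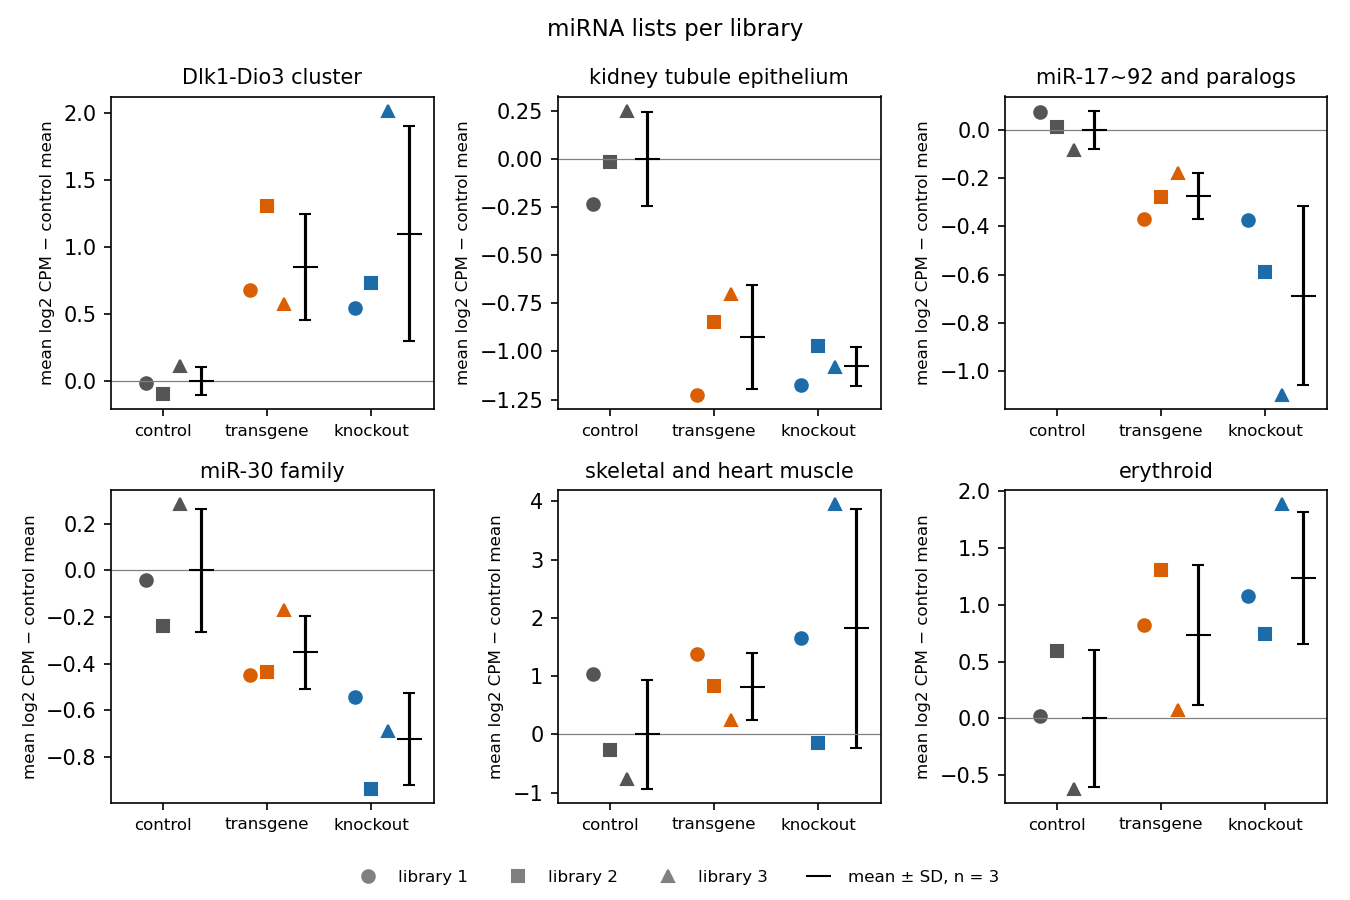
Mean log2 CPM of 6 miRNA lists in each library, as the difference from the control mean, with the group mean and SD (n = 3). The Dlk1-Dio3 means of all transgene and knockout libraries lie above the controls and the tubule means lie below them, and knockout 3 is the highest library for the Dlk1-Dio3, muscle and erythroid lists.

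Tubule and proliferation miRNAs were lower in the knockout. The tubule list fell with a median of -1.23 and all 8 members negative (camera adjusted p = 0.0014, or adjusted p = 0.190 with an estimated correlation). miR-192-5p was at 758 ± 21.1 against 2079 ± 1009 CPM (log2 -1.45, SE 0.39) and miR-204-5p at 1275 ± 415 against 2150 ± 149 CPM (log2 -0.75, SE 0.31, and -0.43 without knockout 3 for mmu-miR-204-5p, knockout vs control). The miR-17~92 clusters fell with a median of -0.64 and all 25 members negative (adjusted p = 4.4e-08, or adjusted p = 0.338 with an estimated correlation). miR-92a-3p was at 13742 ± 2748 against 27041 ± 5723 CPM (log2 -0.98, SE 0.21) and miR-93-5p at 5931 ± 1369 against 10514 ± 2114 CPM (log2 -0.83, SE 0.22). The miR-30 family fell with a median of -0.66 and all 11 members negative (adjusted p = 3.2e-04, or adjusted p = 0.308 with an estimated correlation), miR-30c-5p at -0.71 (SE 0.40) and miR-30d-5p at -0.24 (SE 0.31). The fold of miR-30c-5p was -0.47 without control 3 and -0.43 without knockout 2, and that of miR-30d-5p went from -0.40 without knockout 3 to -0.036 without control 3. Fry, which tests whether a list moves one way and does not compare it with other miRNAs, called the same 3 lists at adjusted p of 0.0076, 0.0487 and 0.0170. It called no other list in the knockout, and 0 with the transgene and 0 between knockout and transgene. By fry the Dlk1-Dio3 list had an adjusted p of 0.102 in the knockout and 0.446 with the transgene. Adjusted over the list alone, 2 tubule, 6 miR-17~92 and 3 miR-30 miRNAs were lower.

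The let-7 family, which restrains proliferation, fell with a median of -0.41 and 19 of 23 members negative (camera adjusted p = 0.0119, or adjusted p = 0.473 with an estimated correlation), let-7i-5p at -0.61 (SE 0.16) and let-7a-5p at -0.35 (SE 0.24). Hox cluster miRNAs fell with a median of -0.58 and 10 of 11 negative (adjusted p = 0.0097, or adjusted p = 0.379 with an estimated correlation), miR-10a-5p at -1.14 (SE 0.32) and miR-10b-5p, from the Hoxd cluster, at -0.58 (SE 0.26). Both calls ended without knockout 3, at medians of -0.25 (adjusted p = 0.153) and -0.27 (adjusted p = 0.102). Without it let-7i-5p stood at -0.38, let-7a-5p at -0.13 and miR-10b-5p at -0.28, and let-7a-5p was at -0.53 without knockout 2. The Sfmbt2 list, defined by name, fell with a median of -0.34 and 42 of 60 negative (adjusted p = 0.0119, or adjusted p = 0.379 with an estimated correlation), miR-467a-5p at -0.64 (SE 0.23) and miR-669b-5p at -0.24 (SE 0.27). The Sfmbt2 list means of the knockout libraries overlapped with controls (exact permutation p 0.3), while those of let-7 and Hox did not (exact p 0.1 each). Of the 60 members of the Sfmbt2 list, 36 had a locus inside the Sfmbt2 gene (chromosome 2:10370510-10595253), with a median of -0.41 and 24 negative, 7 had loci elsewhere only and 17 had none, a division made after the values were seen. The Sfmbt2 list call ended without control 2 (median -0.21, adjusted p = 0.139) and without knockout 2 (-0.45, 0.0613), and the list median was -0.55 without control 3. miR-467a-5p was at -0.42 without control 2, and miR-669b-5p went from -0.43 without knockout 2 to 0.047 without knockout 3. Precursors that bypass DROSHA rose with a median of 1.01 and 13 of 16 positive (adjusted p = 0.0314, or adjusted p = 0.338 with an estimated correlation). Their abundant members miR-484, at 2923 ± 1309 against 2307 ± 176 CPM, and miR-320-3p, at 764 ± 310 against 752 ± 126 CPM, differed by less than the spread. With a filter of at least 10 CPM the list call ended (median 0.09, adjusted p = 0.598), and without knockout 3 the median was 0.48 (adjusted p = 0.0493). The list mean was 4.77 log2 CPM in knockout 3 against 3.83 and 3.75 in knockouts 1 and 2. Because the DROSHA-independent factors are computed from this list, scaling by them subtracts its mean rise from every miRNA.

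In edgeR's quasi-likelihood test no single miRNA passed in the knockout comparison, while 245 of 955 had an unadjusted p under 0.05 (149 higher, 96 lower, where chance gives 47.75) and the smallest adjusted p was 0.108. DESeq2 called 103, 66 higher and 37 lower, among them 39 higher miRNAs of the Dlk1-Dio3 list, 6 higher muscle miRNAs, 4 lower of miR-17~92, 3 lower of miR-30 and 2 lower of the tubule list. Without knockout 1, edgeR called 48, of which 44 were higher, 34 of those on the Dlk1-Dio3 list. miR-673-3p, which lies in the region but is not on the list, was called higher by both. Without control 1 or control 2 the 245 became 160 or 159. Groups did not overlap for 272 miRNAs, or 28.5%, where chance gives 10%. The 5 smallest p-values, none past the threshold, belonged to miR-3067-5p (log2 -4.50, SE 0.83), the neighbours miR-27b-3p (5588 ± 587 against 10716 ± 675 CPM, log2 -0.94, SE 0.18) and miR-23b-3p (3329 ± 215 against 5856 ± 754 CPM, log2 -0.82, SE 0.16) of chromosome 13:63300484-63300784, miR-667-5p (3.38 ± 1.41 against 0.920 ± 0.131 CPM, log2 1.87, SE 0.37) and miR-135b-5p (90.5 ± 14.3 against 218 ± 24.1 CPM, log2 -1.27, SE 0.26). Of the most abundant miRNAs not yet given, miR-26a-5p had a log2 fold of -0.38 (SE 0.17) and miR-126a-3p of -0.20 (SE 0.18), which turned to 0.01 with total counts. Without knockout 3 these were -0.22 and 0.047, and miR-126a-3p was at -0.34 without knockout 2 and -0.10 without control 3.

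Other lists did not pass in the knockout comparison, with medians of -0.57 for miR-200 (camera adjusted p = 0.162), -0.33 for the injury list (0.0916) and -0.07 for endothelium (0.810), the last turning positive with total counts or all counted reads. The medians of 0.34 for miR-99/100 and miR-125 (0.307), 0.41 for stroma and smooth muscle (0.146), 0.55 for leukocytes (0.162), 0.17 for the Igf2 and H19 hosted miRNAs (0.810), 0.35 for miR-34 and miR-449 (0.344) and 0.88 for neural miRNAs with a test direction of down (0.829) turned negative with DROSHA-independent factors. Pancreas and liver miRNAs stood at -0.56 (0.818) and the miR-290 and miR-302 clusters at -1.02 (0.279), each with a test direction of up. Adjusted over the list alone, 1 leukocyte and 1 pancreas and liver miRNA were higher. The share of higher miRNAs at an unadjusted p under 0.05 was 60.8% with TMM, 80.7% with total counts, 72.9% with all counted reads and 7.43% with DROSHA-independent factors. These scalings moved the median of all miRNAs to 0.19, 0.09 and -0.68, and the lowest Dlk1-Dio3 median over 24 alternatives was 0.44.

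**Figure D3:**
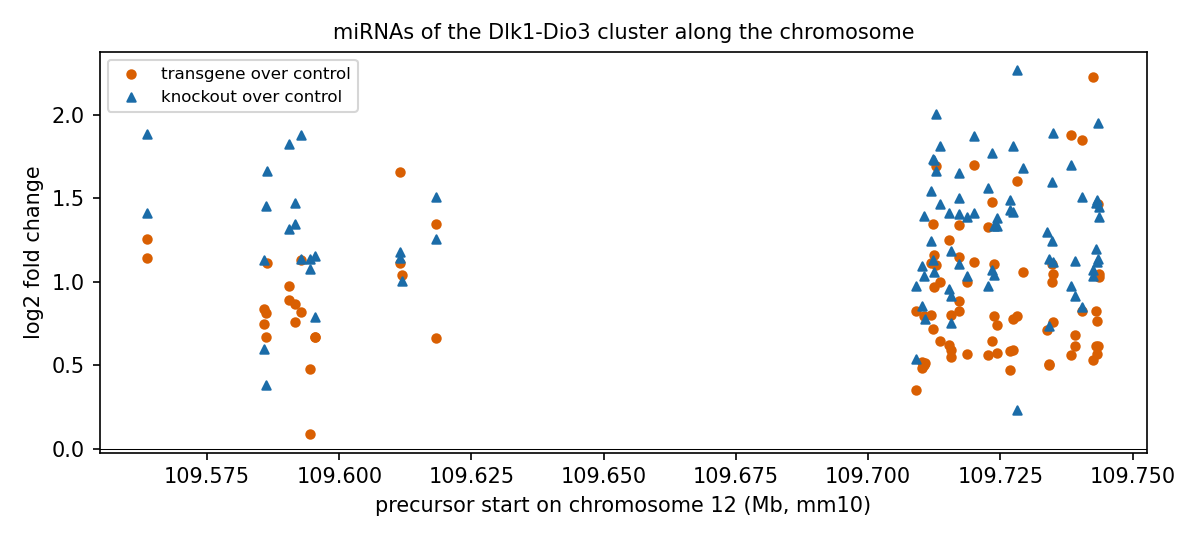
log2 fold change over controls of the 90 miRNAs of the Dlk1-Dio3 list by the start of their precursor on chromosome 12 (Mb, mm10), circles for the transgene and triangles for the knockout, 3 libraries per group. All points lie above 0 along the region from 109563692 to 109743795.

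The direct comparison of knockout with transgene kidneys gave 1 miRNA past the threshold of edgeR, miR-3067-5p, encoded in an intron of Smoc1 on chromosome 12:81166151-81166234. It was counted at 99, 92 and 25 reads in the transgene libraries and at 0, 1 and 1 in the knockouts, against 17, 13 and 24 in controls (log2 -6.39, SE 0.81, adjusted p = 0.0285). On pooled reads as CPM, the transgene exceeded the knockout 99.1-fold (95% exact binomial interval 27.1 to 824) and controls exceeded it 26.6-fold (7.02 to 225). The call ended in 12 of 23 alternatives (adjusted p from 4.9e-05 to 0.284), among them leaving out any 1 library other than transgene 3, from 0.0525 without control 3 to 0.182 without knockout 3. The keratinocyte-associated miR-205-5p (461 ± 126 against 191 ± 35.9 CPM, log2 1.27, SE 0.28), miR-135a-5p (559 ± 169 against 1227 ± 259 CPM, log2 -1.13, SE 0.28), miR-203-3p (log2 0.82, SE 0.21) and miR-203-5p (log2 0.99, SE 0.25) had the next smallest p-values and did not pass (edgeR adjusted p = 0.567). At an unadjusted p under 0.05 there were 67 miRNAs (33 higher, 34 lower, where chance gives 47.75), DESeq2 called 3, namely miR-205-5p and miR-467h higher and miR-3067-5p lower, and groups did not overlap for 99, or 10.4%, where chance gives 10%. miR-467h was chosen after its values were seen.

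Between knockout and transgene, camera called 6 lists. Of the 10 splits of these 6 libraries into 3 and 3, 5, the real one included, called at least as many, and another called 9. These calls therefore do not set the genotypes apart from other groupings. The miR-17~92 clusters fell with a median of -0.40 and 23 of 25 negative (camera adjusted p = 7.4e-06, or adjusted p = 0.437 with an estimated correlation), miR-92a-3p at -0.52 (SE 0.20) and miR-93-5p at -0.29 (SE 0.22). The Sfmbt2 list fell with a median of -0.34 and 48 of 60 negative (adjusted p = 2.4e-05, or adjusted p = 0.434 with an estimated correlation), miR-467a-5p at -0.28 (SE 0.22) and miR-669b-5p at 0.28 (SE 0.27), and 30 of the 36 members inside the gene were negative (median -0.40). The miR-30 family fell with a median of -0.39 and 10 of 11 negative (adjusted p = 0.0102, or adjusted p = 0.437 with an estimated correlation), miR-30c-5p at -0.59 (SE 0.40) and miR-30d-5p at 0.10 (SE 0.31). The miR-34 and miR-449 family, targets of p53 and abundant in ciliated epithelium, rose with a median of 0.66 and all 7 members positive (adjusted p = 0.0032, or adjusted p = 0.434 with an estimated correlation), miR-34a-5p at 0.23 (SE 0.22) and miR-34b-3p at 0.90 (SE 0.38). The miR-99/100 and miR-125 family rose with a median of 0.33 and 8 of 11 positive (adjusted p = 0.0228, or adjusted p = 0.437 with an estimated correlation), miR-99a-5p at 0.33 (SE 0.18) and miR-99b-5p at -0.05 (SE 0.24). Leaving out 1 library moved miR-92a-3p to -0.34 and miR-93-5p to -0.089 (knockout 3), miR-30c-5p to -0.27 (knockout 2), miR-34a-5p to 0.050 (transgene 2) and 0.14 (knockout 1), and miR-34b-3p to 0.60 (transgene 3) and 1.43 (transgene 1). It moved miR-99a-5p to 0.17 (transgene 2) and 0.51 (transgene 1), miR-99b-5p to between -0.21 (knockout 2) and 0.20 (knockout 3), miR-669b-5p to between 0.13 (knockout 2) and 0.49 (knockout 3), and miR-30d-5p to between -0.13 (knockout 3) and 0.31 (knockout 2).

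The Dlk1-Dio3 cluster was called higher in knockout than in transgene libraries with a median of 0.42 and 80 of 90 positive (camera adjusted p = 2.4e-04, or adjusted p = 0.681 with an estimated correlation), miR-127-3p at 0.32 (SE 0.29) and miR-411-5p at 0.37 (SE 0.31), which went from -0.075 and -0.014 without knockout 3 to 0.49 and 0.60 without knockout 1. That call rested on knockout 3, without which the median was -0.08 (adjusted p = 0.209), and on transgene 3 (0.24, 0.0959), while the median was 0.64 without knockout 1 and turned to -0.0023 with DROSHA-independent factors. The Dlk1-Dio3 list means of knockout and transgene libraries overlapped (exact permutation p 0.7). Without knockout 3 the miR-17~92 call ended (median -0.16, adjusted p = 0.0743), as did miR-30 (-0.26, 0.0716) and miR-34 and miR-449 (0.44, 0.0529). The miR-30 call also ended without transgene 3 (-0.30, 0.0959) and knockout 2 (-0.27, 0.0550). The miR-99/100 call ended without transgene 2 (0.17, 0.231), knockout 1 (0.40, 0.0959) and knockout 2 (0.27, 0.0553), and its median turned to -0.0023 with DROSHA-independent factors. Its median was 0.20 without knockout 3, and that of miR-34 and miR-449 was 0.32 without transgene 3.

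The remaining lists did not pass between knockout and transgene, among them muscle with a median of 2.0 (camera adjusted p = 0.0628), the tubule list with -0.40 (0.207), let-7 with -0.30 (0.117), Hox cluster miRNAs with -0.26 (0.0847), DROSHA-independent precursors with 0.72 (0.0851), erythroid with 0.47 (0.10), miR-200 with -0.14 (0.338), endothelium with -0.11 (0.678), pancreas and liver with -0.87 (0.338) and the miR-290 and miR-302 clusters with -1.08 (0.641). Stroma with 0.30 (0.0867), leukocyte with 0.29 (0.396), the injury list with 0.21 (0.447), neural miRNAs with 0.68 (0.338) and the Igf2 and H19 hosted miRNAs with 0.02 (0.890), the last 2 with a test direction of down, turned negative with DROSHA-independent factors. No list was called in any of the 3 comparisons with an estimated correlation. Of the 67 miRNAs at an unadjusted p under 0.05, 49.3% were higher with TMM and 8.20% with DROSHA-independent factors, which moved the median of all miRNAs to -0.27.

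The fold changes of the 2 DROSHA groups were compared across miRNAs. Over the 955 miRNAs, the log2 fold changes of transgene and knockout against controls had a Pearson r of 0.559 (Spearman 0.663), and 77.7% had the same sign. Across miRNAs, which are not independent replicates, unchanged groups simulated with shared controls gave a mean r of 0.491 (range 0.399 to 0.589 over 100 draws). The observed r lay inside that range. The simulated same-sign share was 66.5% (61.9 to 70.3). The covariance was 0.391 against a simulated 0.202 (0.149 to 0.278), a difference of 0.189. Simulated miRNAs were drawn independently, so these ranges may be too narrow for miRNAs that move together. Without knockout 3 the r was 0.264, for which no simulation was run. The 3 controls are too few to be divided into parts of at least 2 libraries, so part of the excess may come from the shared controls.

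**Figure D4:**
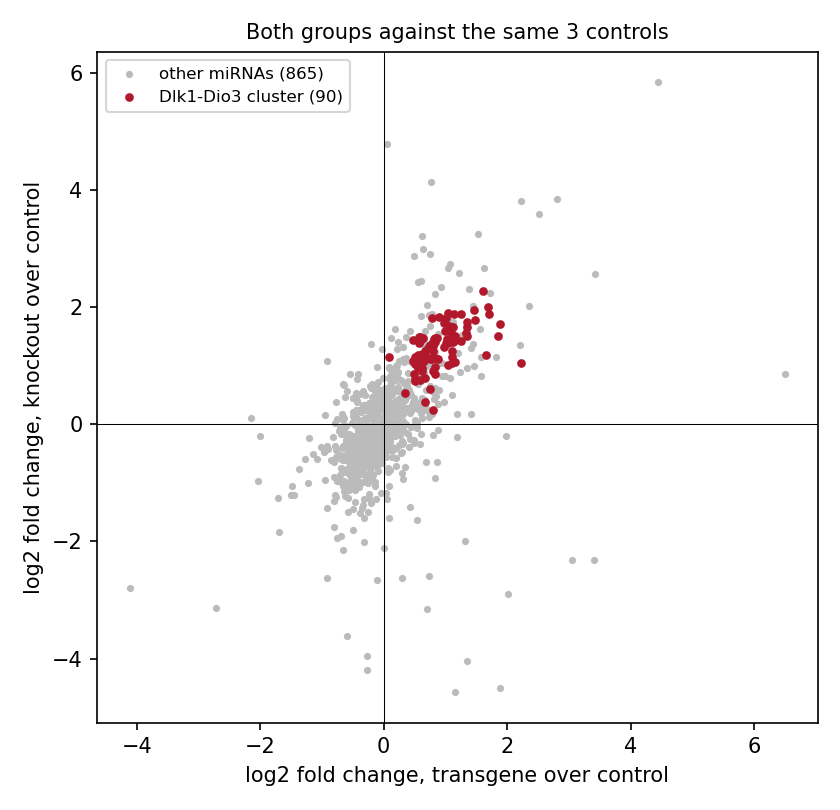
log2 fold change of each of 955 miRNAs with the transgene (x axis) and in the knockout (y axis), both over the same 3 controls, with the 90 miRNAs of the Dlk1-Dio3 list in red. All red points have positive values on both axes.

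Arm use was compared because E1147K lies in one RNase III domain, and each of the enzyme's RNase III domains cuts one strand of the hairpin. The median log2 ratio of 5p to 3p counts over 306 hairpins was 0.65 ± 0.04 in controls, 0.58 ± 0.15 with the transgene and 0.54 ± 0.13 in the knockout (SD, n = 3 each). The differences from controls, -0.07 for the transgene (exact two-sided permutation p 0.5) and -0.11 for the knockout (exact p 0.3), were smaller than the spread between libraries, and the smallest p the design allows is 0.1. The size depended on the measure. Arms summed over hairpins gave -0.13 (exact p 0.2) and -0.37 (exact p 0.1), a filter of at least 10 CPM gave -0.28 and -0.27 (exact p 0.2 each), and no filter gave 0 and -0.059 (exact p 1 each). Leaving out 1 library gave -0.018 (without transgene 2), -0.031 (transgene 3) and -0.15 (transgene 1, exact p 0.1) for the transgene, and -0.049 (without knockout 3) and -0.18 (knockout 2, exact p 0.1) for the knockout. A change in arm use was neither shown nor excluded.

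Counts of miR-199a-3p and miR-199b-3p, abundant in stromal cells, traded places between libraries. miR-199a-3p was the higher of the pair in transgenes 1 and 2 and knockout 1, and miR-199b-3p in the other libraries, while their sum was 26508 ± 1051 CPM in controls, 26528 ± 5518 with the transgene and 32879 ± 3576 in the knockout (SD, n = 3 each). The standard deviation over the 9 libraries was 0.23 for log2 of the sum, against 1.41 and 1.66 for the 2 names alone. Folds of either name alone are therefore not given. Both names were still counted separately in the main tests, including the stroma and smooth muscle list. This pair was chosen after its values were seen.

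**Figure D5:**
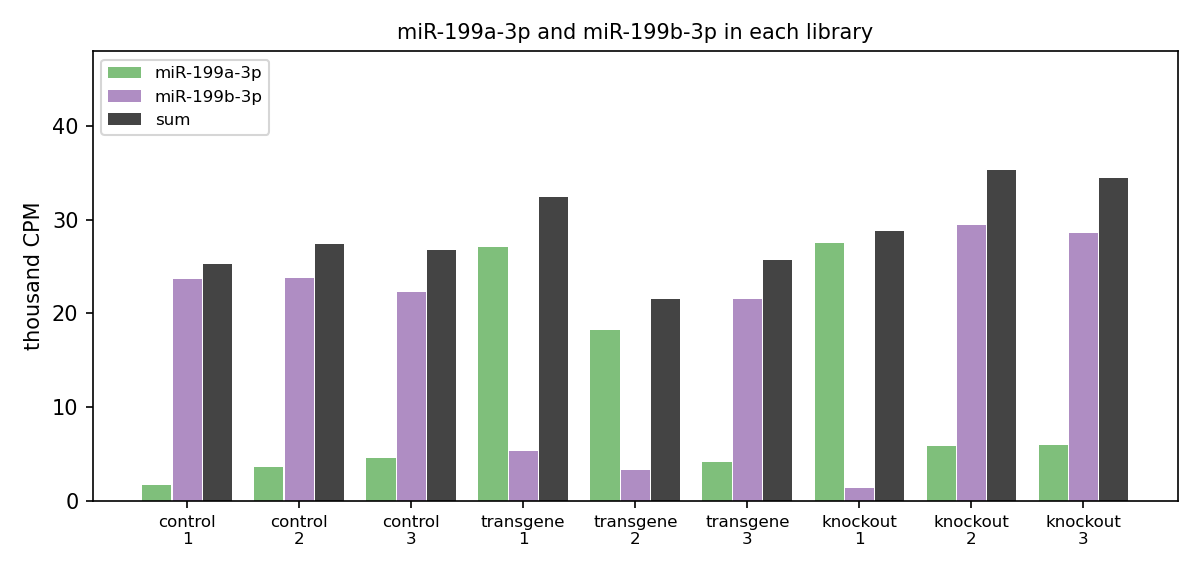
Abundance (kilo-CPM) of miR-199a-3p (green), miR-199b-3p (purple) and their sum (black) in each of the 9 libraries. The sum stays between 21494 and 35335 CPM while the pair of names trades places in transgenes 1 and 2 and knockout 1.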

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

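The 9 counts over other splits, apart from that of miRNAs at an unadjusted p under 0.05 between knockout and transgene, and the muscle and locus tests were chosen before the results were seen; the tests of stroma and endothelium, other tissues, scaling, summed miR-199 reads, breakdown products and Rfam families were chosen after.

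miR-3067-5p differed between the DROSHA groups, at a log2 difference of -6.39 for knockout minus transgene (edgeR adjusted p = 0.0285). Against controls, neither group had a miRNA past the edgeR threshold. Before scaling, transgene libraries held 99, 92 and 25 reads, controls 17, 13 and 24, and knockouts 0, 1 and 1. Transgene 3 was thus close to control 3. miR-205-5p (1.27), miR-203-3p (0.82) and miR-203-5p (0.99) lay below all controls in all 3 transgene libraries and above all controls in all 3 knockouts, although the knockout folds of miR-203-3p (-0.22) and miR-203-5p (-0.069) turned negative with DROSHA-independent factors, and their differences did not pass edgeR (adjusted p = 0.567 each). These 3 names stand out of 955 tested, and miR-203-3p and miR-203-5p come from 1 precursor.

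Some classes outside the miRNA tests were above controls in all 3 libraries of a group. Other Rfam small RNAs took 0.462% of knockout reads against 0.256% in controls, tRNA 0.0566% against 0.0293%, and siRNA 2.44e-04% with the transgene and 2.71e-04% in the knockout against 1.14e-04%. Each had an exact two-sided permutation p of 0.1, the smallest possible, and 0.5 for the transgene and 0.25 for the knockout after adjustment. Chance puts all 3 libraries of a group above all controls in 1 of 20 classes.

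The Dlk1-Dio3 miRNAs were higher in both DROSHA groups. Scaling, which moves all miRNAs alike, was argued against, since the cluster's mean rose over that of all other miRNAs by 0.86 for the transgene and 1.16 for the knockout (SE 0.39 each), or 0.86 (SE 0.22) and 0.75 (SE 0.25) without knockout 3, although medians of the levels gave 0.89 and 0.95 (SE 0.49 each), or 0.89 (SE 0.32) and 0.47 (SE 0.36) without it. Other tissues stay open. The covariate was the mean of the neural, pancreas and liver, leukocyte and erythroid lists. With it the transgene difference went from 0.85 to 0.43 (SE 0.14) and the knockout difference from 1.09 to 0.71 (SE 0.14). Without knockout 3 they were 0.55 (SE 0.13) and 0.65 (SE 0.12). Marker lists measure tissue content imperfectly, so a remaining difference cannot argue against this cause. Muscle tissue stays open, at 0.64 (SE 0.36) and 0.63 (SE 0.42) with the muscle list as a covariate, or 0.89 (SE 0.27) and 0.66 (SE 0.29) without knockout 3, and so do fewer epithelial cells, as the cluster minus stroma and endothelium differed by 0.84 and 0.99 (SE 0.43 each), or 0.84 (SE 0.31) and 0.59 (SE 0.34). Lower DROSHA processing was not tested by any of these. By itself it would lower reads from hairpins that DROSHA releases, whereas all 90 tested members of the list were higher. Values relative to other miRNAs cannot separate a rise from a smaller fall.

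miR-199a-3p and miR-199b-3p traded places between libraries. Reads of 1 shared mature sequence assigned to either name are a candidate explanation, because log2 of their sum had an SD of 0.23 over 9 libraries against 1.41 and 1.66 alone. A change in the use of the miR-199a and miR-199b loci was argued against by the 5p arms, whose ratio had an SD of 0.22 against 2.96 for the 3p arms and an r of -0.28 with it (permutation p 0.463). The assignment rule is not given in the sources used here.

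The mature miRNA share was lower in both DROSHA groups. Reads moved from mature names to Rfam microRNA families were argued against as the whole cause, since with the families added the share still differed by -2.87 and -3.19 points (SE 1.31 each), although the knockout libraries then overlapped controls (exact p 0.2), and by -3.47 and -4.54 with miR-451 also left out (exact p 0.1 each). More breakdown products of other RNAs stay open, because exon, intron, rRNA, tRNA, snRNA, snoRNA and other Rfam reads differed by -0.121 points for the transgene and 0.395 for the knockout (SE 0.368 each), and by 2.73 and 3.10 (SE 1.26 each) with repeat and intergenic reads, whose origin is not given in the sources used here. Lower DROSHA processing could give a lower share and stays open, untested.

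The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. For the transgene, the real split gave 0 miRNAs by edgeR (highest other 0, with 10 splits as large), 7 lists (highest other 6, 1 split as large) and 84 miRNAs at an unadjusted p under 0.05 (highest other 49, 1 split as large), beside 2 by DESeq2. For the knockout it gave 0 miRNAs (highest other 1, 10 splits), 10 lists (highest other 12, 2 splits) and 245 at an unadjusted p under 0.05 (highest other 99, 1 split), beside 103 by DESeq2. Between knockout and transgene it gave 1 miRNA (highest other 2, 3 splits), 6 lists (highest other 9, 5 splits) and 67 at an unadjusted p under 0.05 (highest other 117, 6 splits). The 12 lists came from setting controls 1 and 3 and knockout 2 against the other 3 libraries.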

How the results depend on the processing

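The robust fit, voom, scaling to all counted reads, mature entries only, identical sequences summed the other definitions of the mature share and the alternatives for genomic clusters were added after the data were seen. The alternative for normalized values was not applicable, because the files hold counts. Of 1854 values for single miRNAs under alternatives, 1777 kept their direction and side of the threshold, as did 502 of 551 list medians and 338 of 405 medians of genomic clusters, and 239 of 290 counts, correlations and shares stayed the same. Of 78 single-miRNA values, 42 moved by over 1.5 times when 1 library was left out. Where a value below differs from the report, the cause was not tested.

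The knockout against control count was 2 (both lower) with DROSHA-independent factors and 103 with DESeq2, and 0 to 48 when 1 library was left out. The transgene count was 2 with DESeq2. Between knockout and transgene it was 3 with DESeq2 and 0 with the 10 CPM filter, other small RNAs, voom or only the 2 groups compared, and 0 to 1 when 1 library was left out, and 3 to 11 lists were called. With the replicate number as a block, the count was 0 in each comparison and lists called were 5, 10 and 7. Same-number libraries were not alike (median correlation -0.157 over 9 pairs), so the numbers were not taken as pairs. The correlation of fold changes was 0.430 with DESeq2, 0.429 without a filter, 0.724 with the 10 CPM filter, 0.511 with other small RNAs and 0.619 with only the 2 groups, and 0.264 to 0.617 when 1 library was left out. The mature share differed by -1.14 (transgene) and -3.48 (knockout) points with intron, exon, repeat and intergenic reads left out, and with Rfam families added by -3.19 (knockout) and -0.321 (knockout against transgene).

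Some values near 0 changed sign. With total counts these were mmu-miR-30c-5p (0.13) and mmu-miR-21a-5p (0.10) with the transgene and mmu-miR-126a-3p (0.014) in the knockout. With all counted reads mmu-miR-30c-5p was at 0.067 and mmu-miR-21a-5p at 0.041, and with only the 2 groups mmu-miR-21a-5p, transgene vs control, was at 0.0037. With DROSHA-independent factors the knockout values were -0.21 for mmu-miR-484, -0.65 for mmu-miR-320-3p, -0.22 for mmu-miR-203-3p and -0.069 for mmu-miR-203-5p and -0.083 for the median of the Mir100 to Mir125b-1 cluster, and the knockout against transgene values -0.31 for mmu-miR-30d-5p, -0.0023 for mmu-miR-99a-5p and for the Dlk1-Dio3 median, -0.12 for mmu-miR-127-3p, -0.060 for mmu-miR-411-5p and -0.062 for mmu-miR-34a-5p. With voom they were 0.019 for mmu-miR-30c-5p and -0.056 for mmu-miR-293-3p (transgene), and -0.13 for mmu-miR-30d-5p, 0.10 for mmu-miR-99b-5p (knockout against transgene) and -0.0016 for mmu-miR-127-3p, knockout vs transgene. With the block mmu-miR-320-3p was at -0.016.

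Leaving out 1 library gave, for the transgene, -2.93 to 3.88 for mmu-miR-292a-3p, -2.23 to 2.92 for mmu-miR-293-3p, -0.33 to 0.12 for mmu-miR-30c-5p and -0.34 to 0.089 for mmu-miR-21a-5p. For the knockout it gave -0.25 to 0.27 for mmu-miR-320-3p, -0.0095 to 0.68 for mmu-miR-484, -0.34 to 0.047 for mmu-miR-126a-3p and -0.43 to 0.047 for mmu-miR-669b-5p. For knockout against transgene it gave -0.077 to 0.64 for the Dlk1-Dio3 median, -0.13 to 0.31 for mmu-miR-30d-5p, -0.21 to 0.20 for mmu-miR-99b-5p, -0.075 to 0.49 for mmu-miR-127-3p and -0.014 to 0.60 for mmu-miR-411-5p. Depth limits mmu-miR-3067-5p, with 2 reads in all knockouts.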

Other observations

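The tests of genomic clusters, their alternatives and the miRNAs named here were chosen after the values were seen. Of 34 genomic clusters with at least 4 tested miRNAs, camera called 5 with the transgene (3 higher, 2 lower) and 10 in the knockout (4 higher, 6 lower), and 0 with an estimated correlation. Leaving out 1 library gave 2 (without transgene 1) to 6 for the transgene, with 3 called without control 1, and 7 to 11 for the knockout. With DROSHA-independent factors there were 3 and 6, and with the 10 CPM filter 2 and 6. In each comparison 2 of the 5 or 10 lay in the Dlk1-Dio3 region, and in the knockout 3 belonged to the miR-17~92 list and 1 lay inside Sfmbt2. Of these, the Mir363 to Mir106a call (median -0.64) ended without knockout 3 (-0.31, adjusted p = 0.0739) and with DROSHA-independent factors (0.0639), and the Mir25 to Mir106b call (-0.47) ended without knockout 3 (-0.38, 0.0671), with those factors (0.0639) and with only the 2 groups (0.0512). The Sfmbt2 call (-0.38) ended in 6 of 24 alternatives, among them without control 1 (-0.38, 0.0549), control 2 (-0.32, 0.0884), knockout 1 (-0.29, 0.0751) and knockout 2 (-0.55, 0.0706), and its median was -0.59 without control 3.

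The Mir23b, Mir27b, Mir3074-1 and Mir24-1 cluster (chromosome 13:63300484-63301283) had a median log2 fold of -0.82 in the knockout (camera adjusted p = 0.0012, or adjusted p = 0.262 with an estimated correlation), called in all 24 alternatives. With the transgene it stood at -0.49 (adjusted p = 0.0485, or adjusted p = 0.547 with an estimated correlation), a call that ended in 16 of 24 alternatives, among them leaving out any 1 library other than control 2 or transgene 2, from 0.0552 without knockout 3 to 0.148 without control 1.

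The Mir302 cluster (chromosome 3:127545228-127545689) stood at 1.44 in the knockout (camera adjusted p = 0.0137, or adjusted p = 0.383 with an estimated correlation) and at 0.95 with the transgene (adjusted p = 0.0263, or adjusted p = 0.652 with an estimated correlation). Its calls ended without knockout 2 for the knockout (1.45, 0.0588), and without control 3 (0.85, 0.0776) or transgene 1 (0.58, 0.194) for the transgene. Mir212 with Mir132 (chromosome 11:75173388-75173747) stood at -0.59 with the transgene (adjusted p = 0.0263, or adjusted p = 0.547 with an estimated correlation), and that call ended in 4 of 24 alternatives, without control 1 (-0.52, 0.144) or transgene 1 (-0.71, 0.0943), with DROSHA-independent factors (-0.93, 0.0997) and with the 10 CPM filter (-0.62, 0.0741). Mir100, Mirlet7a-2 and Mir125b-1 (chromosome 9:41531425-41582002) stood at 0.55 in the knockout (adjusted p = 0.0460, or adjusted p = 0.349 with an estimated correlation) and turned to -0.083 with DROSHA-independent factors. That call ended in 14 of 23 alternatives, among them leaving out any 1 library other than control 2 or knockout 3, from 0.0535 without transgene 2 to 0.124 without knockout 2.

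The Mir200a, Mir200b and Mir429 cluster (chromosome 4:156053905-156055750) stood at -0.74 in the knockout (camera adjusted p = 0.0460, or adjusted p = 0.471 with an estimated correlation). It rested on knockout 3, without which the median was -0.33 (adjusted p = 0.200), and the call ended in 13 of 24 alternatives, among them leaving out any 1 library other than control 3 or knockout 2.

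miR-375-3p was at 388, 616 and 329 CPM in controls 1 to 3, 2697, 2502 and 9143 with the transgene, and 737, 2279 and 4856 in the knockout. miR-467h had 46, 7 and 28 reads in controls, 49, 7 and 27 with the transgene, and 25, 1040 and 940 in the knockout.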
